A study of Mus musculus with 9 samples.

How the data were processed

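The samples were PV interneurons sorted for a red fluorescent reporter from cortex and hippocampus, 5 from control and 4 from Arx CKO mice, grouped by their titles. Per the labels' protocols, tissue was dissociated with papain, RNA was extracted with Trizol, and libraries were made with a low-input SMARTer kit. That kit amplifies small amounts of RNA without molecular identifiers, so low counts can be copies of few molecules. Per the labels, 1 Arx CKO sample was run in duplicate and its reads were collapsed, and some samples were sequenced more than once. No sequencing batch is given per sample.

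The authors compared the groups with DESeq2 and the mouse build mm9, per the submitters' processing notes. The DESeq2 version, the aligner and the counter are not given in the sources used here. The deposited table holds 27362 transcripts by RefSeq accession (24720 coding and 2642 noncoding) under 21578 gene symbols. Its mean normalized count is a signal averaged by the authors over all libraries after division by size factors, per the file headers and the values. The fold changes and their standard errors are deposited on the log2 scale, per the file headers. The deposited Wald statistic is a score that equals the log2 fold change over its standard error in every line (largest gap 1.93e-07). The deposited p-values and adjusted p-values are the authors' own, and a Benjamini-Hochberg adjustment repeated over the 23536 transcripts with an adjusted p differed by at most 0.303% of the value. The p in the authors' table was missing for 647 transcripts, and 572 of these had a negative fold change. The adjusted p alone was missing for 3179 transcripts with a mean of 2.30 or lower.

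The table does not state which group is in the numerator. A mean over libraries of counts over size factors is a sum of whole multiples of 1 step per library, so the lowest means give the steps. A search found 9 steps, which explained 310 of 310 distinct means under 0.9 (tolerance 8e-09). Transcripts with at least 2 reads, all in a single library, had positive fold changes for 4 libraries and negative ones for 5. With 5 control and 4 Arx CKO samples, a positive value is therefore higher in Arx CKO. The commonest fold change of the lowest means was -1.23926, against -1.23929 computed for 5 libraries on the negative side and -1.38356 for 4. The decoded libraries were not matched to named samples. On simulated means of 12000 transcripts for this comparison, 53 of 53 steps in the range searched were found with 0 false ones, and 52 of 52 sides were right. The simulated fold change was a log ratio of group means, not a DESeq2 fit. That nearly fixes the sides in advance, so their count says little about the deposited fold changes.

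The design fixed before the data were examined foresaw count tests, with the authors' adjusted p and statistic as the fallback for a table that holds a comparison alone, and that fallback was used. Counts of changed transcripts use the authors' adjusted p under 0.05. For lists and named genes the transcript with the highest mean stood for a gene, which gave 18021 tested genes. Symbols were spelled by the RefSeq gene table of GRCm38.p6, where 26785 of the accessions matched; its coordinates were not used, since the authors' build differs. There were 83 transcripts without a symbol and 43 whose symbol was a plain number, and the accession gave a symbol for the latter where it matched.

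Named genes followed a rule fixed beforehand. It takes Arx, the 12 changed genes with the largest fold change in each direction with a mean above the median of tested genes, and up to 4 members of each list with the smallest p along with any past the threshold. The 26 lists fixed beforehand cover reported Arx targets, interneuron transcription factors, cell type markers, channels, receptors, synaptic, matrix, stress, metabolic, sex-linked and immune genes. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited statistic, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. This test compares a list with all other genes, whose statistic averaged -0.25. It can therefore point up where a list's own median is below 0, as for interneuron transcription factors, axon guidance and adhesion and immediate early genes. The sex-linked list had a negative mean statistic and a median above 0. An estimated correlation and fry need values per sample, so a preset correlation of 0.05 and 10000 random lists matched on mean expression stood in for them. On simulated statistics of 18021 genes, 3.365% of unchanged lists had a cameraPR p under 0.05, and 100% of lists moved by 0.5 on the log2 scale were found. The lists moved were those of presynaptic release, collagens and basement membrane, cytosolic ribosomal proteins and oxidative phosphorylation, with 31 to 74 members. How often a smaller list would be found was not simulated. With matched random lists, 3 of 26 unchanged lists had a p under 0.05 in a first simulation, and 4.904% did over 40 more, run after the results were seen. The simulated unchanged genes were independent of each other, with no trend with expression. These rates therefore do not show how often either test errs on correlated genes such as those measured here.

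Alternatives before the data were examined that could be run were no filter on the mean, an adjusted p under 0.1, and a change of at least 2-fold. Added after seeing the data were 1 transcript per gene, a mean count of at least 100, a correlation of 0.05, matched random lists, and the transcript with the smallest p per gene. Lists of choroid plexus, leptomeningeal fibroblast, motile cilia and sensory receptor genes were also added then. Transcript lengths came from GENCODE M21. Other computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.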

Results

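RNA was sequenced from parvalbumin (PV) interneurons, a class of inhibitory neurons, that carried a red fluorescent reporter and were sorted by flow cytometry from mouse cortex and hippocampus. The mice were between postnatal days 35 and 40. There were 5 control mice with Cre recombinase under the Pvalb promoter and 4 mice that also carried a floxed copy of Arx (Arx CKO). Arx encodes a homeobox transcription factor of the interneuron lineage, and the comparison addressed which transcripts differ once it is deleted in these cells. All values below rest on the authors' deposited table, which gives for each of 27362 RefSeq transcripts a mean normalized count over all libraries, a log2 fold change with its standard error, and an adjusted p. Because that table has 1 line per transcript and none per sample, spread between mice enters only through the standard error. Fold changes are given as Arx CKO over control. The relative depth of the 9 libraries, decoded from the lowest mean counts, ran from a size factor of 0.434 to 2.92, a 6.73-fold range. Total read numbers are unknown.

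**Figure D1:**
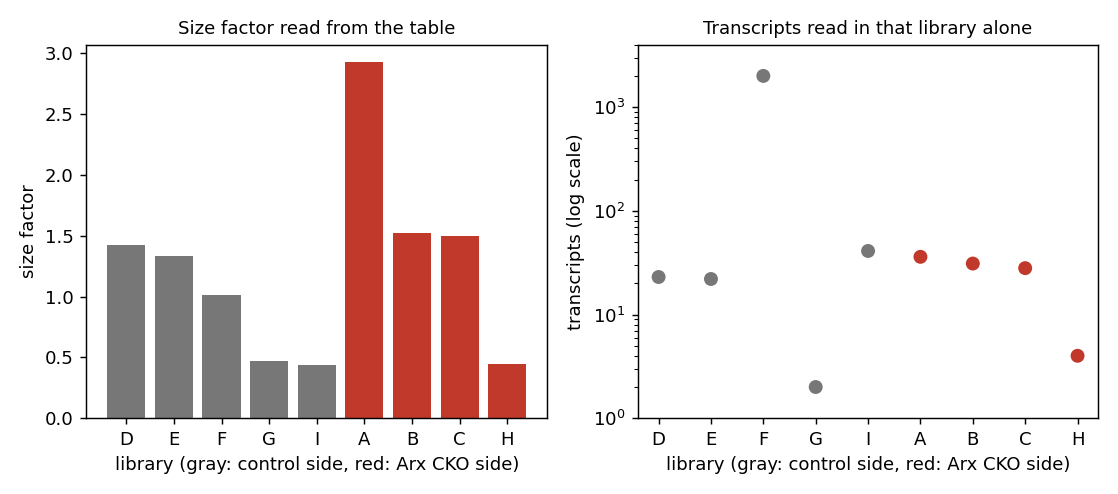
Size factor (left) and number of transcripts read in that library alone (right, log scale) for the 9 libraries decoded from the lowest mean counts, with libraries on the control side in gray and on the Arx CKO side in red. Library F on the control side held 1998 such transcripts, against 2 to 41 in the other control-side libraries.

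The sorted material held abundant glial transcripts beside those of interneurons. In the authors' deposited table the mean normalized count was 838472 for Plp1 and 276341 for Mbp, which encode myelin proteins, and 62898 for Csf1r, a microglial receptor. By comparison the same authors' deposited table gave 2415 for Gad1, an enzyme of GABA synthesis, and 132.5 for Pvalb. None of these 5 genes passed the threshold between the groups, with log2 fold changes in the authors' deposited table of 0.12 for Plp1, -0.04 for Mbp, -0.40 for Csf1r, -0.07 for Gad1 and 0.35 for Pvalb.

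Transcripts of neurons were among those higher in Arx CKO, and transcripts of extracellular matrix and epithelial proteins were among those lower. Of 23536 transcripts with an adjusted p in the authors' deposited table, 195 passed the threshold of 0.05, and these belonged to 159 gene symbols. There were 49 transcripts higher and 146 lower in Arx CKO, so that 74.9% were lower. The authors' deposited table gave a median log2 fold change of 1.17 for the higher and -3.40 for the lower transcripts, with median mean counts of 761 and 97.0. All 40 changed transcripts with a mean count under 30 were lower. The control-side library F held 1998 transcripts read in no other library, with a 99th percentile of mean count of 7.80 and a highest of 32.0. Of these, 0 passed the threshold, so they are not among the 40. Duxf3, Smok2a and Olfr1406 were among the 40, and their means were matched by reads mostly in library F and some in 1 other control-side library. Only pairs of libraries that include library F were searched for this match. With transcripts of a mean count of at least 100 alone, adjusted again, 114 transcripts passed, 44 higher and 70 lower (61.4% lower).

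**Figure D2:**
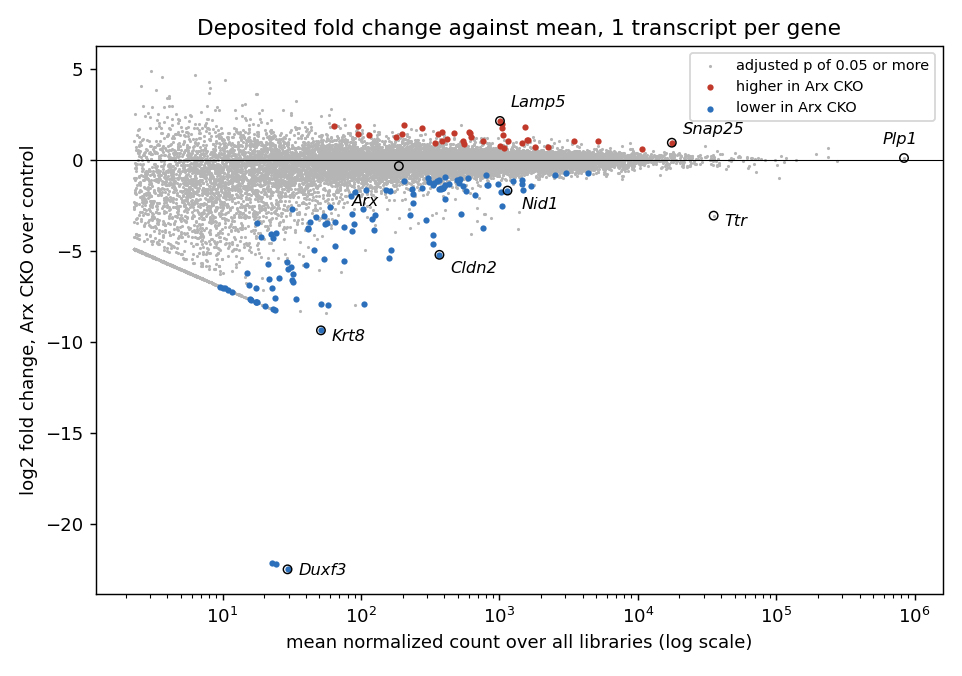
Log2 fold change of Arx CKO over control against the mean normalized count over all libraries (log scale), 1 point per gene with an adjusted p, from the authors' deposited table. Red points (higher) and blue points (lower) passed the threshold of 0.05, gray points did not, and circles mark named genes. Changed genes at low means lay on the lower side, and Plp1 lay near 0 at a mean of 838472.

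The 12 genes with the largest positive fold changes, among changed genes with a mean above 363, included several of neuronal signalling. The authors' deposited table gave Lamp5, a membrane protein of a class of cortical interneurons, a log2 fold change of 2.16 (SE 0.41, adjusted p = 0.000283). Gria3, an AMPA receptor subunit, had 1.99 (SE 0.44, adjusted p = 0.00333) in the authors' deposited table, and Cck, a neuropeptide, 1.83 (SE 0.47, adjusted p = 0.0216). The synaptic vesicle protein gene Sv2b stood at 1.79 (SE 0.50) and Cacng3, an auxiliary subunit of AMPA receptors, at 1.57 (SE 0.33) in the authors' deposited table. Nrn1, which encodes neuritin, was at 1.56 (SE 0.36), and Neurod6, a transcription factor of excitatory neurons, at 1.49 (SE 0.34), again in the authors' deposited table. The rest of the 12 in the authors' deposited table were Tmem59l (1.47, SE 0.39), Mal2 (1.41, SE 0.37), Zdhhc2 (1.25, SE 0.31), Ralyl (1.15, SE 0.32) and Hpca, a neuronal calcium sensor (1.10, SE 0.23).

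The 12 genes with the largest negative fold changes under the same rule were led by Cldn2, a tight junction protein, at -5.21 (SE 1.22, adjusted p = 0.00696) in the authors' deposited table. Cldn2 also stands on the list of choroid plexus markers, and Col1a1 and Col3a1 below on that of leptomeningeal fibroblast markers. Both lists were drawn up after the values were seen. Car12, a carbonic anhydrase, followed at -3.73 (SE 0.81, adjusted p = 0.00253) in the authors' deposited table, and Slc2a12, a sugar transporter, at -2.96 (SE 0.60, adjusted p = 0.000709). Sulf1, an extracellular sulfatase that acts on heparan sulfate, was at -2.51 (SE 0.49), and Vat1l at -2.16 (SE 0.54), in the authors' deposited table. Matrix genes of this set in the authors' deposited table were Fn1, fibronectin (-1.91, SE 0.48), Col1a1 (-1.78, SE 0.43), Col18a1 (-1.68, SE 0.46), Nid1, the basement membrane protein nidogen (-1.67, SE 0.32), and Col3a1 (-1.65, SE 0.40). Aebp1 (-1.61, SE 0.45, adjusted p = 0.0457) and Reck (-1.57, SE 0.34) completed it in the authors' deposited table, and Aebp1 had an adjusted p = 0.0519 when no transcript was filtered out on its mean.

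**Figure D3:**
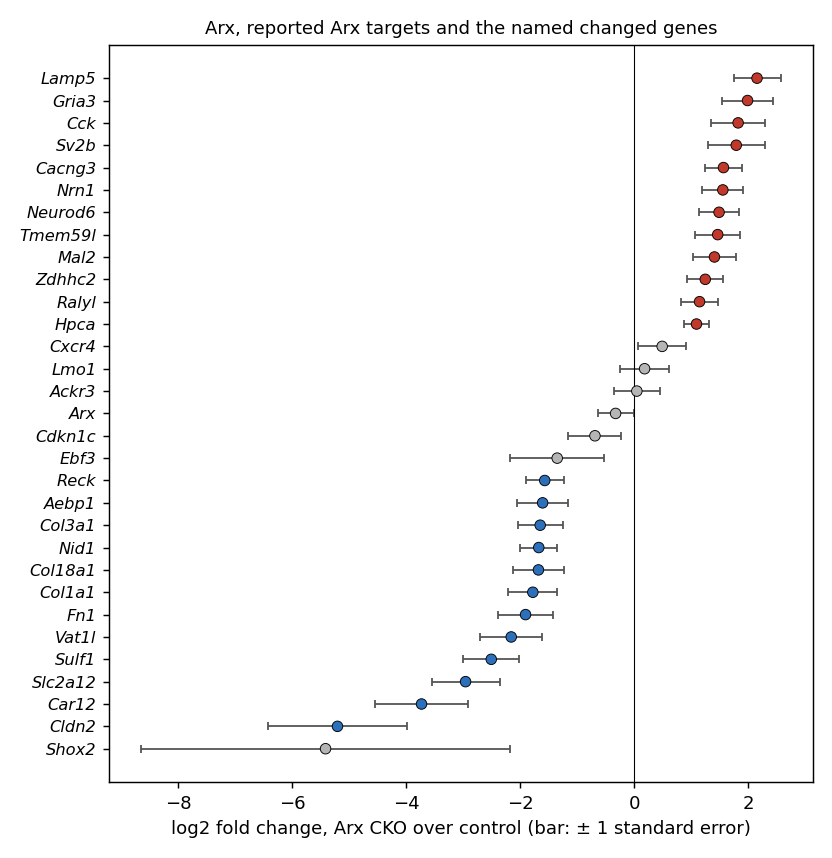
Log2 fold change of Arx CKO over control with bars of 1 standard error, from the authors' deposited table, for Arx, the 6 reported Arx targets and the 12 changed genes with the largest fold change in each direction. Red and blue points passed the threshold of 0.05 and gray points did not. Arx lay at -0.33 with a standard error of 0.32.

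Arx itself did not differ between the groups past the threshold. Transcript NM_007492 of Arx had a log2 fold change of -0.33 (SE 0.32, adjusted p = 0.793) at a mean normalized count of 188 in the authors' deposited table. The 95% interval made from that standard error ran from -0.95 to 0.30. The floxed part of the gene is not given in the sources used here, and reads over exons that remain after deletion would still be counted. This value therefore does not check the labels of the samples.

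None of the 6 reported Arx targets passed the threshold, and as a list they did not differ from other genes (cameraPR adjusted p = 0.681). In the authors' deposited table Ebf3 had a log2 fold change of -1.35 (SE 0.82), Cdkn1c -0.69 (SE 0.46) and Cxcr4 0.49 (SE 0.43). Shox2 had -5.42 (SE 3.24) at a mean of 3.33 in the authors' deposited table. Of 16 tested interneuron transcription factors, 0 rose and 0 fell (cameraPR adjusted p = 0.910), with Npas1 at 1.11 (SE 0.58) and Dlx5 at -0.88 (SE 0.60) in the authors' deposited table. The list counts adjusted over the list alone were also 0 for both.

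PV interneuron markers did not separate from other genes, whereas markers of other interneurons and of excitatory neurons did. Of 17 PV markers none passed the threshold, 11 had a positive and 6 a negative fold change in the authors' deposited table, and the median was 0.09 (cameraPR adjusted p = 0.307; 0 adjusted over the list alone). Examples from the authors' deposited table are Kcnc2, a fast potassium channel (0.77, SE 0.38), Slc6a1, a GABA transporter (-0.82, SE 0.35), Erbb4 (0.35, SE 0.37) and Nefh (-0.58, SE 0.45). Of 22 markers of other interneurons, 3 rose, namely Lamp5, Cck and Calb1, and 19 did not pass. The median was 0.37 in the authors' deposited table (cameraPR adjusted p = 8.02e-05). Their fold changes there were positive for 15 and negative for 7, among the latter Ndnf (-0.69, SE 0.54) and Adarb2 (-0.44, SE 0.49). Calb1, a calcium-binding protein, had 1.09 (SE 0.27) and Sst, which did not pass, 1.27 (SE 0.43) in the authors' deposited table. Which cells the transcripts of Lamp5, Cck and Calb1 came from is unknown, since the sorted samples held transcripts of other cells as well. Adjusted over the list alone, 5 rose and 1 fell. The mean statistic of the PV markers lay below that of the markers of other interneurons and excitatory neurons together without passing the threshold (permutation p = 0.0797 across genes, which are not independent).

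Of 19 excitatory neuron markers, Neurod6 and Nrgn rose and 17 did not pass, with a median of 0.42 in the authors' deposited table (cameraPR adjusted p = 0.000243; 3 rose adjusted over the list alone). Nrgn, a calmodulin-binding postsynaptic protein, had 1.05 (SE 0.26) in the authors' deposited table. The vesicular glutamate transporter genes Slc17a7 (1.24, SE 0.45) and Slc17a6 (2.42, SE 1.08) did not pass in the authors' deposited table.

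Synaptic and channel genes lay higher in Arx CKO as lists, along with the excitatory neuron markers above, and few single members passed the threshold. Of 34 genes of presynaptic release, Sv2b and Snap25 rose and 32 did not pass (cameraPR adjusted p = 1.98e-07; 5 rose adjusted over the list alone). Snap25, a SNARE protein, had 0.96 (SE 0.22) and Syt1, its calcium sensor partner, 1.12 (SE 0.36, not passed) in the authors' deposited table. Of 30 glutamate receptor and postsynaptic genes, Gria3 rose and 29 did not pass (cameraPR adjusted p = 0.000263; 1 rose adjusted over the list alone). Of 34 sodium, calcium and HCN channel genes, Cacng3 rose, whose product acts on AMPA receptors, and 33 did not pass (cameraPR adjusted p = 3.14e-05). Adjusted over the list alone 2 rose, Cacng3 and Cacng2. Scn1a, the sodium channel gene of Dravet syndrome, had 1.17 (SE 0.42, adjusted p = 0.205) in the authors' deposited table. There 24 of the 34 fold changes were positive and 10 negative, among the latter Hcn2 (-0.82, SE 0.48) and Hcn3 (-1.02, SE 0.71). All 53 potassium channel genes missed the threshold singly, while the list passed (cameraPR adjusted p = 0.000462; 4 rose adjusted over the list alone). Kcnip4 came nearest at 1.28 (SE 0.37, adjusted p = 0.0518) in the authors' deposited table, beside Kcnv1 at 1.94 (SE 0.62).

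The 25 GABA genes and 40 epilepsy genes held no member past the threshold. As lists they passed (cameraPR adjusted p = 0.00656 and adjusted p = 0.0209), but with a preset correlation of 0.05 between genes neither did (adjusted p = 0.0583 and adjusted p = 0.146). Gabra1, the main alpha subunit of the GABA-A receptor, had 1.27 (SE 0.37, adjusted p = 0.0649) in the authors' deposited table, and Slc6a11, an astrocytic GABA transporter, -0.96 (SE 0.33). Adjusted over the list alone, 3 GABA genes rose and 1 fell, and 1 epilepsy gene rose.

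**Figure D4:**
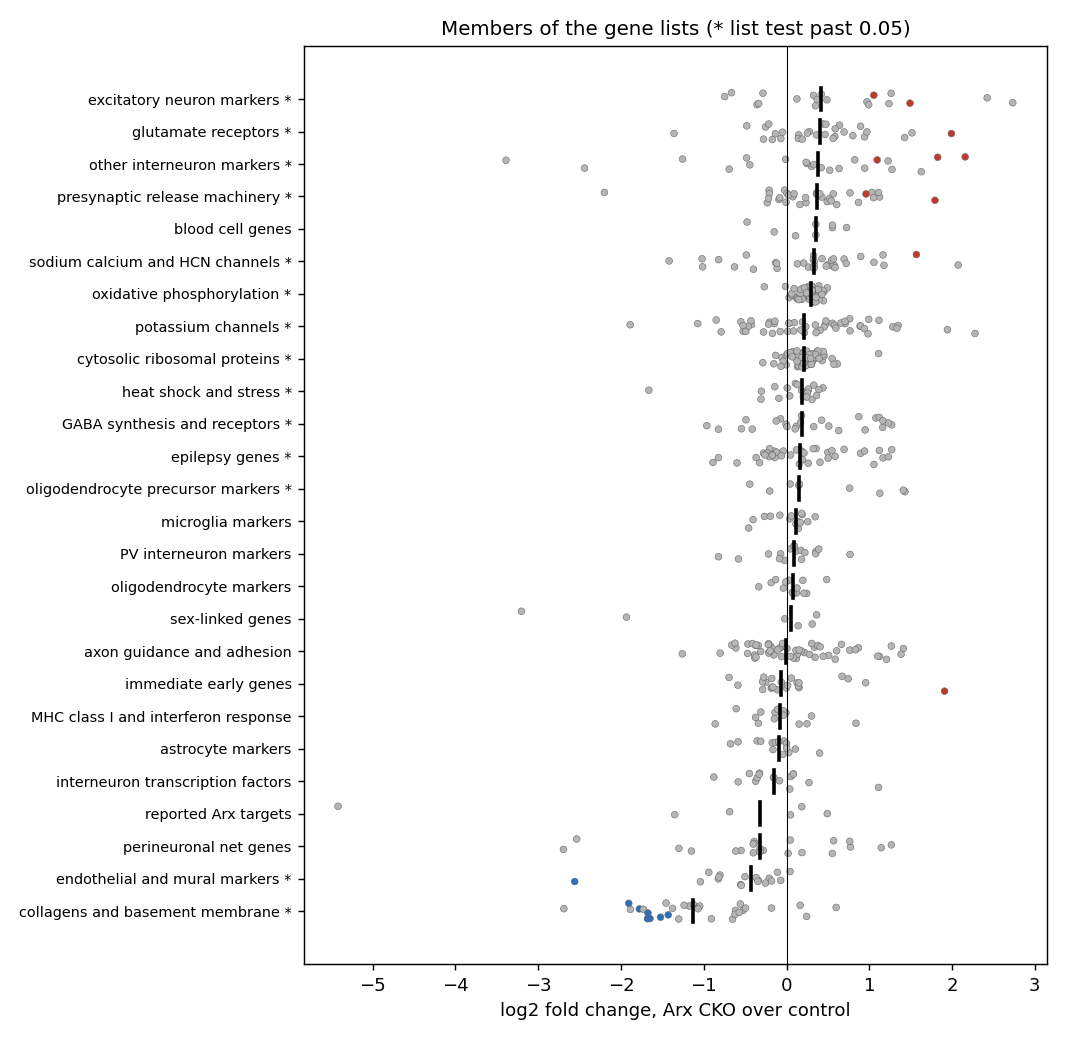
Log2 fold change of Arx CKO over control for each tested member of the 26 gene lists, from the authors' deposited table, with the list median as a black bar. Red and blue points passed the threshold of 0.05 singly, and a star marks lists with a cameraPR adjusted p under 0.05. The medians ran from -1.13 for collagens and basement membrane to 0.42 for excitatory neuron markers.

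Collagen and basement membrane genes were lower in Arx CKO. Of 31 members, 8 fell, 0 rose and 23 did not pass, and 28 had a negative fold change in the authors' deposited table, with a median of -1.13 (cameraPR adjusted p = 2.65e-15; 19 fell adjusted over the list alone). Beside the matrix genes above, the authors' deposited table gave Col1a2 at -1.43 (SE 0.34, adjusted p = 0.00847), Lamb1, a laminin chain, at -1.52 (SE 0.42, adjusted p = 0.0417), and Col6a1 at -1.06 (SE 0.28, adjusted p = 0.0261). Of 18 endothelial and mural markers, 17 were negative in the authors' deposited table, with a median of -0.43 (cameraPR adjusted p = 0.00245). Cdh5, the cadherin of endothelial junctions, fell at -2.56 (SE 0.54, adjusted p = 0.00133) at a mean count of 59.7 in the authors' deposited table. It was the single member past the threshold over all genes and adjusted over the list alone. At means of 679 and 1226 there, Cldn5 had -0.34 (SE 0.42) and Ly6c1 0.04 (SE 0.53). Kdr, a VEGF receptor, had -1.04 (SE 0.42) and Pdgfrb, a pericyte receptor, -0.82 (SE 0.40) in the authors' deposited table, and neither passed. Markers of the choroid plexus, a list drawn up after the values were seen, were lower along with these genes, with all 20 fold changes negative and a median of -3.13 in the authors' deposited table.

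As lists, genes of energy metabolism and translation lay higher than other genes, whose statistic averaged -0.25, and no single member passed the threshold. Of 70 oxidative phosphorylation genes, 68 had a positive fold change in the authors' deposited table and none passed singly (median 0.30, cameraPR adjusted p = 3.37e-08). Ndufs3, a complex I subunit, had 0.45 (SE 0.27) and Cox5a, a cytochrome oxidase subunit, 0.39 (SE 0.30) in the authors' deposited table. Of 74 cytosolic ribosomal protein genes, 66 were positive in the authors' deposited table and none passed (median 0.21, cameraPR adjusted p = 2.42e-05), for example Rpl29 at 0.61 (SE 0.31). The 20 heat shock and stress genes had a median of 0.19 in the authors' deposited table and no member past the threshold, with Hspa8 at 0.33 (SE 0.21). That list passed (cameraPR adjusted p = 0.0171) but not with a preset correlation of 0.05 (adjusted p = 0.0796). Adjusted over the list alone, 0 genes of these 3 lists passed.

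Glial and immune lists held no gene past the threshold. The 15 astrocyte markers had a median of -0.10 in the authors' deposited table (cameraPR adjusted p = 0.564), with the transcription factor Sox9 at -0.68 (SE 0.33) and Fgfr3 at -0.59 (SE 0.28). Against random lists matched on expression the astrocyte list was lower (permutation adjusted p = 0.0288). The 14 oligodendrocyte markers had a median of 0.07 in the authors' deposited table (cameraPR adjusted p = 0.181), with Opalin at 0.49 (SE 0.30), and the 16 microglia markers 0.12 (cameraPR adjusted p = 0.240), with Ctss at 0.35 (SE 0.23). The 9 oligodendrocyte precursor markers passed as a list (median 0.16 in the authors' deposited table, cameraPR adjusted p = 0.0358) but not with a preset correlation of 0.05 (adjusted p = 0.0796). C1ql1 of that list had 1.43 (SE 0.57, not passed) in the authors' deposited table. The 8 tested blood cell genes had a median of 0.35 in the authors' deposited table (cameraPR adjusted p = 0.240), and Hba-a1 and Hba-a2, near-identical copies, carried the same values there. The 16 genes of MHC class I and the interferon response had a median of -0.07 in the authors' deposited table (cameraPR adjusted p = 0.910), with Tap1 at -0.86 (SE 0.48). Adjusted over the list alone, 0 genes of these 6 lists passed.

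The remaining lists did not differ from other genes. The 22 perineuronal net genes had a median of -0.32 in the authors' deposited table (cameraPR adjusted p = 0.326), and their members with the smallest p were Otx2 (-2.69, SE 0.87) and Adamts15, a matrix protease (-2.53, SE 0.87), the 2 that fell adjusted over the list alone. Otx2 is also 1 of the choroid plexus markers, which had a median of -3.13 in the authors' deposited table. With genes of a mean count of at least 100 the perineuronal net list was lower (cameraPR adjusted p = 0.0347). Of 23 immediate early genes, Bdnf, a neurotrophin, rose at 1.91 (SE 0.51, adjusted p = 0.0298) in the authors' deposited table, also when adjusted over the list alone, and 22 did not pass (cameraPR adjusted p = 0.326). The 58 axon guidance and adhesion genes had a median of -0.01 in the authors' deposited table (cameraPR adjusted p = 0.122), with Epha4 at 0.66 (SE 0.26) and Plxnb1 at -0.80 (SE 0.28). The 6 sex-linked genes did not pass (cameraPR adjusted p = 0.813), with the Y-linked Eif2s3y at 0.31 (SE 0.26) and Kdm5d at 0.36 (SE 0.34) in the authors' deposited table, and Xist, which overlaps its antisense gene Tsix, at a mean of 7.15 and at -1.93 (SE 2.10). No member of these last 2 lists passed when adjusted over the list alone.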

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

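The test on sequencing depth in this part was chosen after the result was seen, and the tests on transcript length and on the share of reads on few transcripts before. In 1 decoded library on the control side, 1998 transcripts had reads there and in no other library, against 23, 22, 2 and 41 in the other control-side libraries. Its gap to the nearest library was 0.980 of the whole range, above the limit of 0.710 for 5 libraries, which chance passes in about 5% of groups. These transcripts held 20090 reads, with a median of 5 and a 99th percentile of mean count of 7.80, and 214 of them had no p. The tables argue against deeper sequencing, since the library with the largest size factor held 36 such transcripts. Genomic DNA or other reads spread over all transcripts stay open, with a Spearman rho of 0.25 between read number and transcript length over 1909 transcripts, which are not independent replicates. RNA of another tissue was to show as reads on few transcripts, but the top 1% of these transcripts held 9.64% of the reads. That share lay just below the limit set beforehand as counting against this source. It stays open only because the bootstrap interval (8.05 to 11.8) reaches above that limit. No biological explanation was tested, because a single library of a group is concerned.

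The 3 transcripts with the smallest p in the authors' deposited table, Duxf3, Smok2a and Olfr1406, had log2 fold changes of -22.51, -22.24 and -22.16. Their mean counts were matched by reads in that library (241, 186 and 186) and in 1 further control-side library (12, 15 and 10) within 1.5e-07, and by no other pair that includes that library.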

How the results depend on the processing

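The settings of a mean count of at least 100, of 1 transcript per gene and all those for the lists were chosen after the results were seen. Alternatives that need values per sample were not run: other normalizations, upper quartile scaling, DESeq2 and limma-voom refits, a surrogate variable, each sample left out in turn, other pseudocounts, and other splits of the samples. The stricter filter in CPM was replaced by a mean count of at least 100. No paired analysis was possible because the deposited comparison has no columns that carry a replicate number. The count of 195 changed transcripts was 186 with no filter on the mean, all 186 among the main ones, 178 with at least 2-fold change, and 159 with 1 transcript per gene. It rose to 319 at an adjusted p under 0.1 and was 114 at a mean count of at least 100, where fewer transcripts were tested. There the share that was lower was 61.4%, since 73 lower but 3 higher transcripts among the 195 had a mean under 100. Under the other settings this share stayed between 71.8% and 78.1%. Arx kept an adjusted p of 0.815 without a filter and of 0.823 at the higher mean. Of the 24 genes named for their size, 23 passed without a filter and 23 at the higher mean, Aebp1 being the exception both times (adjusted p = 0.0519 and adjusted p = 0.0530). Of the 26 lists 14 passed, and 10 with a preset correlation of 0.05, 14 with the smallest p per gene, 12 at the higher mean and 12 against matched random lists. Precursor, GABA, epilepsy and stress lists were the ones lost under at least 1 setting, and the astrocyte and perineuronal net lists each passed under 1. Directions turned for the interneuron transcription factors (adjusted p = 0.815) and the sensory receptors (adjusted p = 0.533) at the higher mean, and for the sex-linked genes with the smallest p per gene (adjusted p = 0.909). The standard error sets what depth allows: its median was 2.32 in the 10% of genes with the lowest mean and 0.25 in the 10% with the highest.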

Other observations

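All lists and tests in this part were chosen after the values were seen, except the test of the trend with expression level. Genes of the choroid plexus epithelium, the tissue that makes cerebrospinal fluid, were lower in Arx CKO. In the authors' deposited table all 20 markers had a negative fold change with a median of -3.13 and 7 of them fell (cameraPR adjusted p = 1.55e-28). The test of a list drawn up after seeing the values is not independent evidence of its direction. The keratin genes Krt8 (-9.36, SE 1.43) and Krt18 (-3.82, SE 0.85), Ace (-4.61, SE 1.20) and the water channel gene Aqp1 (-2.99, SE 0.80) were among them in the authors' deposited table. Of the most abundant markers, Enpp2, which oligodendrocytes also express, had -0.99 (SE 0.33, adjusted p = 0.152) at a mean of 105568, and Ttr, the transthyretin gene, -3.05 (SE 0.98, adjusted p = 0.120) at a mean of 35331 in the authors' deposited table. Of 15 leptomeningeal fibroblast markers 6 fell, among them Col1a1, Col1a2 and Col3a1, which also count among the collagens, and 5 of the 15 stand on another list. Others were Lepr at -1.88 (SE 0.47) and Slc22a6 at -1.42 (SE 0.39) in the authors' deposited table (cameraPR adjusted p = 6.54e-12). The median of these 15 markers was -0.94 there, with 14 negative and 1 positive. Dcn (-0.43, SE 0.40, mean 4494) and Lum (-0.55, SE 0.44, mean 1359) did not pass in the authors' deposited table. Of 13 motile cilia genes 5 fell, with Rsph1 at -2.68 (SE 0.56) and Dnah11 at -3.68 (SE 0.84) in the authors' deposited table (cameraPR adjusted p = 7.47e-12). The other 8 did not pass, among them Foxj1 at -0.13 (SE 0.54) and a mean of 137 in the authors' deposited table. Of the 13 fold changes there, 12 were negative and 1 positive. The 154 tested olfactory, vomeronasal, taste and trace-amine receptors had a median of -4.97 at a median mean of 4.55 in the authors' deposited table, and 4 fell (cameraPR adjusted p = 2.76e-14). With genes of a mean count of at least 100 that list pointed up (adjusted p = 0.533). Its median mean lay below the 99th percentile of 7.80 of the transcripts read in control-side library F alone, and 20 of the 154 were such transcripts.

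Whether the fall of choroid plexus, collagen and basement membrane genes rests on background reads of the control-side library that stood apart stays open. The median mean count of the 51 genes was 390.1, against a 99th percentile of 7.80 for the transcripts read in that library alone, but transcripts absent elsewhere do not show what it adds to genes read in several libraries. A candidate explanation is fewer choroid plexus and meningeal cells in the Arx CKO libraries. The sort for the reporter does not rule out other cells here or below, since Plp1 had a mean count of 838472 and Pvalb 132.5 in the authors' deposited table. The 13 choroid markers that missed the threshold had a median of -2.94, which decides nothing, since the list was drawn up after its fall was seen. Loss of Arx within the sorted cells stays open too: the Arx log2 fold change of -0.33 does not bear on it, as exons left after deletion would still be counted. That explanation also requires that the sorted PV interneurons make these choroid plexus and matrix transcripts, which was not tested. How many libraries carry the difference is unknown.

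Markers of excitatory neurons and other interneurons may be higher in Arx CKO for technical reasons as well. The trend of the statistic with expression level does not account for them, since 0 of 10000 random lists matched on mean expression, 0% of them, reached their mean statistic of 0.95. A larger share of neurons of every kind in the Arx CKO libraries stays open. The mean statistic was 0.13 for 17 PV markers and 0.95 for 41 other markers. That difference had a permutation p = 0.0797 across genes, which are not independent. It does not tell a larger share of every kind of neuron from a larger share of the other kinds alone. Sorted PV interneurons should hold few such neurons, yet the sort left glial transcripts in. The synaptic and channel lists, which were higher too, are open to the same explanation. A change in gene expression through loss of Arx was not tested against it.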
